A study of Homo sapiens with 16 samples.

How the data were processed

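The series measured open chromatin by Omni-ATAC in MCF7 cells and in 2 resistant lines derived from them, with 50000 nuclei per library and 75 bp paired reads, per the labels. There were 8 groups of 2 libraries: parental cells with DMSO, 500 nM abemaciclib, 300 nM INX-315 or both drugs for 7 days, and LYR and LYFR cells, each with DMSO or 300 nM INX-315 on top of the drugs the line was kept in (500 nM abemaciclib, and for LYFR also 100 nM fulvestrant). The cells were fresh or cryopreserved per the labels, which do not say which library was which, so this was not tested. Per the submitters' processing notes, the upstream software was BWA 0.7.17, Picard 3.0.0, SAMtools 1.9, bedtools 2.27.1, Genrich and deepTools 3.5.0 on hg38; the role and the settings of each tool and the version of Genrich were not given in the sources used here.

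The authors deposited 1 peak list per group, made from its 2 libraries together, and these 8 lists were the files used here. Each peak has a summit, a -log10 p at the summit given by the authors (smallest value per list 3.64 to 3.74) and a score, the area under the curve of significance over the peak, also computed by the authors before the files were deposited (smallest value 100 in each list). The area grows with peak width. It was used to rank and select peaks within a list and to match draws and simulated presence, and the ranks it gives were compared between lists of equal length. Values per library and depth per library were not used here. The labels state 30 to 40 M read pairs per library, so the precision that depth gives could not be computed. The median peak width per list was 237 to 251 bp. Peaks on contigs other than chromosomes 1 to 22 and X (311 to 726 per list) were left out of the comparisons.

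The definitions, the gene lists, the motifs and the rules for naming genes were chosen before the data were examined, except where the text says that a choice came after. A gained site was a peak among the 50000 with the highest area of the first list that overlapped no peak of the whole second list by 1 bp, and a lost site was the reverse; the other peaks of the 50000 were common sites. The smallest area among the 50000 was 911 to 1089 per list. There were 10 comparisons. A promoter site had its summit within 1 kb of a transcription start of any transcript in GENCODE release 44, and the other sites were distal. The promoter of a gene was open when the list had a summit within 1 kb of the start of one of its protein-coding transcripts. It was closed otherwise, also where a peak covered the promoter with its summit further away. Sites were assigned to the nearest protein-coding transcription start within 100 kb. With 1 list per group no p-value was computed, and intervals for shares are exact 95% binomial intervals.

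For 22 motifs, written as consensus patterns (1 mismatch allowed for ERE, p53 and HNF1), the share of distal sites with a match within 100 bp of the summit was compared with that of common distal sites and with 10000 draws of common distal sites matched on GC content in 20 bins. AP-1, ERE, FOX, GATA, TEAD, CTCF and E2F were named throughout for gained sites, and other motifs where the share was at least 1.5 or at most 0.67 times that of common sites; other motifs carried by fewer than 5 changed sites, a limit set after the values were seen, were left to the tables, as were some fixed motifs of lost sites. For 12 fixed gene lists (277 genes, all found among 19618 protein-coding genes) gained minus lost sites were set against 10000 random lists of genes matched on number of sites, as a percentile. Genes named were the 10 with the most gained and the 10 with the most lost sites per comparison, the 3 members of each list with the largest difference (at least 2 sites), and CDK2, CDK4, CDK6, CCNE1, CCNE2, CCND1, RB1, CDKN1A, ESR1 and FOSL1, which are named in a comparison where a site near them changed; the strongest site was given for the first 3 genes in each direction. Genes were ranked by counts and not by the share of their sites that changed, so genes with many peaks nearby can rank high. Genes with equal counts were ordered by a fixed rule, and not every gene that met these rules is named in the text.

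Changed sites were also looked up in the other lists. The share present was set against 100 simulated draws in which presence followed that of common sites of the same list with the same area. Common sites have a peak in the other list compared by definition, and changed sites have none. Presence below the simulated value in lists that resemble that other list therefore follows in part from the definition. Overlaps between comparisons were set against the number for independent sets, n1 x n2 / N. This number takes every one of the highest peaks as equally able to change, so it can be too low where changed sites are weaker peaks.

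Alternatives changed 1 choice at a time: the 25000 highest peaks, all deposited peaks, lists of equal length (156188 peaks by -log10 p), ranking by -log10 p, 50% of the peak covered as overlap, 50 bp for motifs, promoters included, promoters within 2 kb and genes within 50 kb. Leaving out 5 Mb windows in which the number of the 50000 highest peaks differed 2-fold or more (50 or more in either list) was added after the data were seen.

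Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The procedures were tested on simulated data: 200 of 200 planted losses and 200 of 200 planted gains were recovered with 0 other sites called, 0 of 4400 planted motif copies were missed, and 8 of 200 random gene lists without an effect lay outside the middle 95%. Peaks missing from the other list were checked with bedtools 2.31.1 in 20 directed comparisons, with 0 differences.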

Results

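Open chromatin was measured by ATAC-seq, which marks DNA that a transposase can reach, in MCF7, an oestrogen receptor-positive breast cancer cell line. The 16 libraries fell into 8 groups of 2. Parental cells had 7 days of DMSO, of 500 nM abemaciclib (an inhibitor of CDK4 and CDK6), of 300 nM INX-315 (described in the series title as a selective CDK2 inhibitor) or of both drugs. LYR cells, resistant to abemaciclib, were kept in 500 nM abemaciclib, and LYFR cells, resistant to abemaciclib and to the oestrogen receptor degrader fulvestrant, in 500 nM abemaciclib and 100 nM fulvestrant; each line was treated with DMSO or 300 nM INX-315. The files used hold 1 combined peak list per group, so no value has a replicate error and no p-value could be given. The labels state 30 to 40 M read pairs per library, and the files give no depth. On chromosomes 1 to 22 and X the lists held 156188 peaks (parental DMSO), 196291 (abemaciclib), 166992 (INX-315), 179271 (both drugs), 190700 (LYR), 206627 (LYR with INX-315), 191409 (LYFR) and 211174 (LYFR with INX-315). A gained site was a peak among the 50000 with the highest area under the curve in the first list that overlapped no peak of the second list, and a lost site was the mirror; common sites were the rest of the 50000. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. Coordinates are on hg38, and the state of a promoter is given for the 2 lists compared.

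Promoters of E2F target genes and of the cell cycle regulators named here were open in every list. All 30 E2F target genes, which drive DNA replication and mitosis, had a peak at their promoter in all 8 lists, and so did CDK2, CDK4, CDK6, CCNE1, CCNE2, CCND1, RB1, CDKN1A, ESR1 and FOSL1. Of 19618 protein-coding genes, 14142 had an open promoter in the parental DMSO list and 13412 had one in all 8 lists. The 2 lists most alike were those of abemaciclib alone and with INX-315, with a Jaccard index of base pairs of 0.793, followed by parental DMSO and INX-315 at 0.773. Parental DMSO and LYFR with INX-315 were the least alike, at 0.557. Parental DMSO and abemaciclib had 0.661, parental DMSO and LYR 0.710, and parental DMSO and LYFR 0.631.

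The comparison of abemaciclib with DMSO asked which sites open or close in parental cells when CDK4 and CDK6 are inhibited. The genes with the most gained sites were PMEPA1, a membrane protein that restrains TGF-beta signalling (7 gained, 0 lost), and GPRC5A, a retinoic acid-inducible receptor (6 gained, 0 lost). Both promoters were open in both lists. Both lists together had 57 of the highest peaks near PMEPA1 and 28 near GPRC5A, against 6 near TAF1L, which had 3 gained sites. Sites were lost near NR4A2, an immediate-early nuclear receptor (0 gained, 3 lost), and RARA, the retinoic acid receptor alpha (0 gained, 2 lost), whose promoters were open in both lists. Distal gained sites carried the AP-1 motif, bound by FOS and JUN factors, in 36.6% of cases, against 21.2% of common distal sites. The p53 motif was present in 1.42% of gained distal sites and in 0.128% of common ones, and with all deposited peaks in 0.356% and 0.0903%.

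In all, 1718 sites were gained (3.44% of the 50000, 3.28 to 3.60) and 128 were lost (0.256%, 0.214 to 0.304). TAF1L, TMEM247, ABCC12, CEP128, MCC, POU5F1B, SYBU and AAK1 each had 3 gained and 0 lost sites; the promoters of TAF1L, TMEM247 and POU5F1B were closed in both lists and those of the others open in both. TEDC1 had 2 lost sites and an open promoter in both lists. AKT3, a kinase of the PI3K pathway, and ANO7 each lost 1 site and had an open promoter in the DMSO list and none in the abemaciclib list. CCR1 and SLC66A1 each lost 1 site with an open promoter in both lists, MYOD1 and VHLL 1 site with a closed promoter in both, and none of these genes gained a site. The strongest gained site near PMEPA1 lay in its intron (chromosome 20, 57656576 to 57658158, area 2796), and that near GPRC5A covered a coding exon next to a transcription start (chromosome 12, 12906901 to 12909517, area 6324). That near TAF1L lay outside protein-coding genes (chromosome 9, 32627398 to 32627919, area 2042). The strongest lost sites were at NR4A2 (chromosome 2, 156325927 to 156328510, area 4333, coding exon, 509 bp from a transcription start), near TEDC1 (chromosome 14, 105502431 to 105503162, area 1458) and near RARA (chromosome 17, 40306763 to 40307467, area 2391, 2110 bp from a transcription start).

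Promoters made up 9.55% of the gained sites (8.20 to 11.03), 21.1% of the lost sites (14.4 to 29.2) and 35.3% of the common sites. The AP-1 motif was found in 568 of 1554 gained distal sites (34.2 to 39.0%), above every draw of common sites matched on GC content (highest 27.1%), and in 6 of 101 lost distal sites (5.94%, 2.21 to 12.5) against 14.4% of common ones. TEAD, the motif of the YAP-responsive factors, was found in 15.2% of gained and 11.2% of common distal sites (highest matched draw 15.0%), and p53 in 22 of 1554 gained sites (0.889 to 2.14%; highest matched draw 0.515%). FOX (18.3% against 15.4%) and GATA (13.8% against 10.1%) lay inside the range of the matched draws, 17.6 to 25.3% and 11.6 to 17.3%. STAT was found in 1.48% of gained against 0.910% of common sites, GRHL in 1.29% against 2.68%, AP-2 in 6.24% against 11.1%, CTCF in 0.0644% against 5.19%, E2F in 0.0644% against 0.564% and ERE, the oestrogen response element, in 0.579% against 0.862%. Among lost sites, ERE was found in 6 of 101 (5.94%, 2.21 to 12.5; highest matched draw 5.94%) against 0.959% of common sites, NFY in 6.93% against 2.86%, RUNX in 4.95% against 2.94%, TEAD in 3.96% against 10.2%, FOX in 12.9% against 13.4% and GATA in 9.90% against 9.25%.

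All 12 gene lists lay in the middle 95% of random lists. EGFR, a growth factor receptor, had 2 gained and 0 lost sites with an open promoter in both lists. Luminal breast identity genes had 0 gained and 0 lost sites (percentile 4.30), and senescence-associated secretory genes 4 gained and 0 lost (percentile 88.6). The window with the highest gained share was chromosome 5 from 50000001 to 55000000, with 9 of 48 sites (18.8%, 8.95 to 32.6). The number of gained sites was 200 among the 25000 highest peaks and 57547 among all deposited peaks, and with all deposited peaks the AP-1 motif was found in 21.1% of gained and 12.8% of common distal sites. With lists of equal length the lost sites numbered 350, against 1718 gained.

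**Figure D1:**
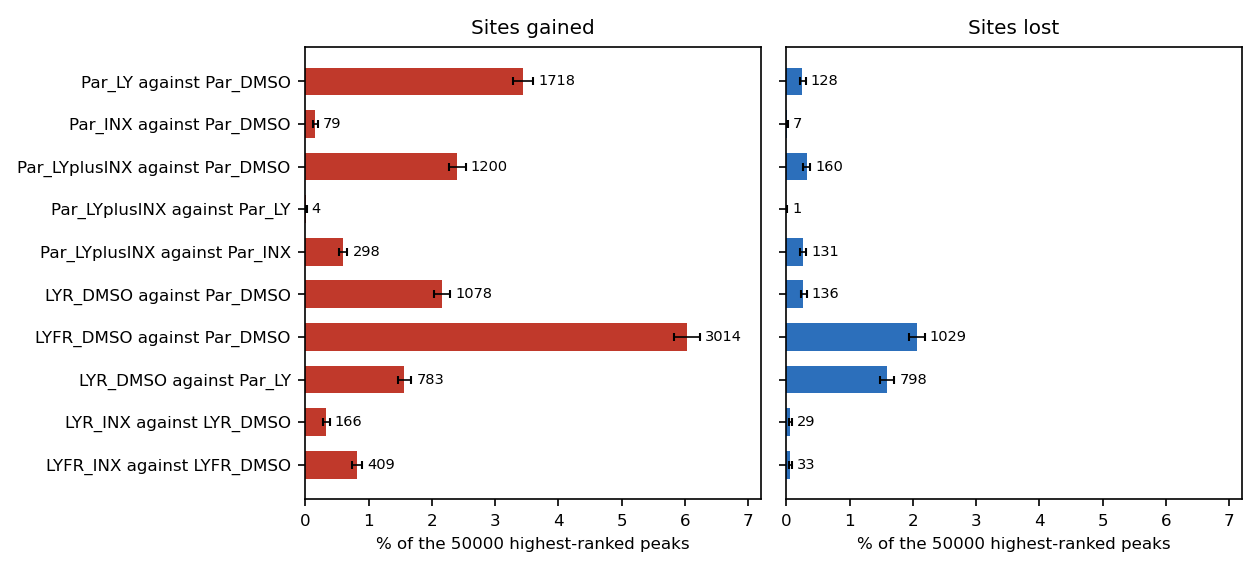
Gained (left, red) and lost (right, blue) sites in the 10 comparisons, as a percent of the 50000 highest peaks, with their number beside each bar and exact 95% binomial intervals that cover counting error only (Par, parental; LY, abemaciclib; INX, INX-315). LYFR against parental DMSO had the most of both, 3014 gained and 1029 lost, and the combination against abemaciclib the fewest, 4 and 1.

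The comparison of INX-315 with DMSO asked the same of CDK2 inhibition alone. Few sites differed: DOK5, an adaptor of receptor tyrosine kinases, had 2 gained and 0 lost sites (promoter open in both lists), and no other gene had more than 1 of either. Distal gained sites carried the GATA motif in 26.03% of cases, against 10.1% of common distal sites. These sites were few, and the share lay inside the range of draws matched on GC content. The AP-1 motif, raised in the abemaciclib comparison, was found in 12.3% of gained and 15.8% of common distal sites.

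The counts were 79 gained sites (0.158%, 0.125 to 0.197) and 7 lost sites (0.0140%). ATP6V1G3, GRXCR1, SLC22A25, SPRR4 and TCEAL2 had 1 gained site each and a closed promoter in both lists. EEF1A2, EXO1, an exonuclease of DNA repair, and TMEM212 had 1 gained site each and a promoter open in both lists, and MAP3K7CL had 1 gained site and a promoter open in the DMSO list only. CTNNA2 lost 1 site and its open promoter, and IFITM10, ZNF331, NR4A3, SEPTIN9 and ENSG00000285188 lost 1 site each with a promoter open in both lists. Among gained sites the strongest lay in introns of DOK5 (chromosome 20, 54532024 to 54533079, area 926) and ATP6V1G3 (chromosome 1, 198534557 to 198535017, area 1060.0) and near GRXCR1 (chromosome 4, 42824390 to 42824914, area 1106). The strongest lost sites lay in introns of CTNNA2 (chromosome 2, 79512440 to 79513083, area 1028) and IFITM10 (chromosome 11, 1739067 to 1740061, area 1198) and near ENSG00000285188 (chromosome 19, 18257387 to 18259244, area 1893). GATA was found in 19 of 73 sites (16.5 to 37.6%), inside the range of the matched draws (highest 32.9%), and AP-2 in 19.2% against 12.2%. FOX was found in 15.1% against 13.7% and TEAD in 13.7% against 11.03%, and ERE, CTCF and E2F in 0 of 73, which allows shares up to 4.93%. Growth factor receptors and adaptors had 2 gained and 0 lost sites (percentile 99.2), 1 each near EGFR and MET, which were chosen after their values were seen; both promoters were open in both lists. The other 11 lists lay between percentiles 37.9 and 94.2. Among the 25000 highest peaks there were 0 gained and 0 lost sites, and 17 and 0 when peaks were ranked by the authors' -log10 p.

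The combination was compared with DMSO, with abemaciclib and with INX-315 to separate the part of each drug. Against DMSO it had the pattern of abemaciclib: PMEPA1 had 8 gained and 0 lost sites, GPRC5A 6 and 0, and EGFR 3 and 0, with promoters open in both lists, and RARA had 0 gained and 2 lost sites. The AP-1 motif was found in 34.9% of gained and 19.4% of common distal sites. Against abemaciclib alone, only 4 sites were gained and 1 was lost.

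Against DMSO, 1200 sites were gained (2.40%, 2.268 to 2.54) and 160 lost (0.320%, 0.272 to 0.374). DDX23, MRPL46, DGKH, AAK1, PDE1C, C3orf14 and SPTBN1 had 3 gained and 0 lost sites with promoters open in both lists, and POU5F1B 3 and 0 with a closed promoter; ranked by the authors' -log10 p, the gained minus lost count near C3orf14 was -1. IKZF2, a lymphoid zinc finger factor, RARA and TANC1 had 0 gained and 2 lost sites with promoters open in both lists. AKT3, GARIN5B and H4C12 lost 1 site and their open promoter, ERBB4 and SLC66A1 lost 1 site with a promoter open in both lists, and VHLL lost 1 site with a closed one. The strongest gained sites were in an intron of PMEPA1 (chromosome 20, 57656268 to 57658133, area 2967), at GPRC5A (chromosome 12, 12907588 to 12909231, area 3681) and near DDX23 (chromosome 12, 48855257 to 48856083, area 2519.6), and the strongest lost sites near IKZF2 (chromosome 2, 213175674 to 213176188, area 1295) and RARA (chromosome 17, 40306763 to 40307467, area 2391) and in an intron of TANC1 (chromosome 2, 159044793 to 159045469, area 1273). Of 1085 gained distal sites 379 carried AP-1 (32.1 to 37.9%; highest matched draw 25.8%). TEAD was found in 14.7% against 10.8%, p53 in 0.829% against 0.134%, FOX in 17.4% against 14.7%, GATA in 10.97% against 9.55%, ERE in 0.553% against 0.900%, GRHL in 0.922% against 2.54% and CTCF in 0.0922% against 5.53%. E2F was found in 0 of 1085. Lost distal sites carried ERE in 3.94% of cases (1.29 to 8.95) against 0.963%, AP-1 in 7.09% against 14.4%, NFY in 4.72% against 2.86% and IRF in 3.94% against 1.73%. All 12 gene lists lay in the middle 95% of random lists, with senescence-associated secretory genes highest (4 gained, 0 lost, percentile 95.7). The number of gained sites was 109 among the 25000 highest peaks and 45625 among all deposited peaks, and with lists of equal length 309 sites were lost.

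Of the 1718 sites gained with abemaciclib, 927 overlapped a site gained with the combination, where n1 x n2 / N for independent sets was 38.1. In the combination list 99.9% of the 1718 sites had a peak and 54.4% were among its 50000 highest; 83.8% would have been there had the DMSO list merely missed common sites of the same strength. In the INX-315 list 64.96% of them had a peak (simulated 99.8%) and 2.15% were among its 50000 highest (simulated 74.95%). The simulated values come from common sites, which have a peak in DMSO by definition. The INX-315 list is close to that of DMSO (Jaccard index 0.773), so part of the shortfall follows from the definition. Sites gained with abemaciclib and with INX-315 shared 36 sites (2.34 for independent sets), and those gained with INX-315 and with the combination 35 (1.66). These overlaps have the DMSO list in common, which raises them by an amount that 1 list does not show.

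Against abemaciclib alone, the 4 sites gained with the combination lay near APPBP2 (chromosome 17, 60538199 to 60539474, area 1351), NCOA3, a coactivator of nuclear receptors (chromosome 20, 47474045 to 47474783, area 1067), BCAS1 (chromosome 20, 53909639 to 53910563, area 1523) and ZMYND8. The lost site lay in an intron of CEP162 (chromosome 6, 84225230 to 84225685, area 1118). Each of these genes had 1 changed site and a promoter open in both lists. Near APPBP2, NCOA3, BCAS1 and ZMYND8 both lists together had 34, 129, 150 and 168 of the highest peaks. The changed site was thus a small part of the peaks there. All 12 gene lists had 0 gained and 0 lost sites. With lists of equal length there were 66 gained and 6 lost sites, and among all deposited peaks the direction turned, with 14158 gained and 30330 lost. Against INX-315 alone, 298 sites were gained (0.596%) and 131 lost (0.262%). ELMO1, NRXN3, PDE1C, DNAH5, GAS7, HK2, a hexokinase of glycolysis, RIPK4 and PMEPA1 had 2 gained and 0 lost sites, and PLXNC1, NFE2L3 and CRISPLD2 0 gained and 2 lost, all with promoters open in both lists. ACTL7A and C12orf54 gained 1 site with a closed promoter. FUOM and LPAR1, a lysophosphatidic acid receptor, lost 1 site with promoters open in both lists, GK2, IL18BP, NLGN3 and ODF4 lost 1 with closed promoters, and H4C12 lost 1 and its open promoter. The strongest gained sites lay in introns of ELMO1 (chromosome 7, 36971427 to 36971806, area 1018), NRXN3 (chromosome 14, 78752855 to 78753246, area 1196) and PDE1C (chromosome 7, 31986910 to 31987479, area 1596), and the strongest lost sites near PLXNC1 (chromosome 12, 94059495 to 94060242, area 1614), NFE2L3 (chromosome 7, 26179524 to 26180611, area 1408) and CRISPLD2 (chromosome 16, 84818896 to 84819417, area 1111).

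Of the 271 distal sites gained with the combination against INX-315, 89 carried AP-1 (32.8%, 27.3 to 38.8) against 19.8% of common ones. The p53 motif was found in 1.85% against 0.143%, IRF in 2.95% against 1.79%, FOX in 21.0% against 14.7%, TEAD in 11.1% against 10.9%, GATA in 8.49% against 9.61% and ERE in 0.738% against 0.889%, and CTCF and E2F in 0 of 271. Of 112 lost distal sites 26 carried GATA (23.2%, 15.8 to 32.1; highest matched draw 26.8%) against 10.1%, 5.36% carried NFY against 2.82%, 4.46% GRHL against 2.76% and 6.25% AP-1 against 15.9%. All 12 gene lists lay between percentiles 4.19 and 85.8.

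The comparison of LYR cells with parental DMSO cells asked which sites differ once cells have become resistant to abemaciclib. LYR cells had abemaciclib in the medium and parental DMSO cells did not, so drug and resistance cannot be told apart in this comparison. Sites were gained near CACNA1H, a T-type calcium channel (6 gained, 0 lost), SNX29 (5 and 0), AUTS2 (4 and 0) and HDAC4, a histone deacetylase (4 and 0), with promoters open in both lists. Sites were lost along the short arm of chromosome 12, near CREBL2, PLBD1, PLEKHA5, BORCS5, SLC2A3, a glucose transporter, ETV6, a transcription factor, and CD9, a tetraspanin (0 gained, 2 lost each). From 5000001 to 31000000 on that chromosome, bounds chosen after the peaks were seen, the LYR list had 77 of its 50000 highest peaks, where parental DMSO had 322. The number of copies of this region was not measured. The AP-1 motif was found in 19.7% of gained and 18.3% of common distal sites, and NFY, the CCAAT-box motif, in 7.43% against 3.61%.

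There were 1078 gained sites (2.16%, 2.03 to 2.29) and 136 lost (0.272%, 0.228 to 0.322), and promoters made up 16.3% of gained and 37.2% of common sites. SEMA3A, a guidance cue, had 3 gained and 0 lost sites and a promoter open in the LYR list only; AACS, EIPR1, LMTK2 and OXR1 had 3 and 0 with promoters open in both lists, and C8orf90 3 and 0 with a closed one. The promoters of CREBL2, PLBD1, PLEKHA5, BORCS5, ETV6 and CD9 were open in both lists and that of SLC2A3 was closed in both. DSCAM, a cell adhesion molecule, had 0 gained and 2 lost sites with a closed promoter, and BMAL2 and CTNNA2 lost 1 site and their open promoter. The strongest gained sites were in introns of CACNA1H (chromosome 16, 1192737 to 1194106, area 6512), SNX29 (chromosome 16, 12027044 to 12027534, area 2321) and AUTS2 (chromosome 7, 70571350 to 70571961, area 2215), and the strongest lost sites near CREBL2 (chromosome 12, 12592925 to 12593266, area 1032), PLBD1 (chromosome 12, 14537236 to 14537722, area 1372) and PLEKHA5 (chromosome 12, 19129925 to 19130469, area 1471). Of 902 gained distal sites 178 carried AP-1 (17.2 to 22.5%) and 67 NFY (5.80 to 9.34%; highest matched draw 5.99%). IRF, the motif of interferon regulatory factors, was found in 2.77% against 1.83%, GATA in 6.43% against 8.36%, FOX in 16.3% against 14.3%, TEAD in 9.09% against 9.81%, ERE in 1.11% against 1.03%, GRHL in 1.11% against 2.42%, E2F in 0.333% against 0.696% and CTCF in 0.111% against 5.28%. Among 115 lost distal sites GATA was found in 14.8% against 9.23%, GRHL in 5.22% against 2.79%, AP-1 in 9.57% against 14.4% and ERE in 1.74% against 0.972%. All 12 gene lists lay between percentiles 10.7 and 78.7. The window from 25000001 to 30000000 on chromosome 12 had the highest lost share, 7 of 51 sites (13.7%, 5.70 to 26.3). Gained sites numbered 179 among the 25000 highest peaks and 47578 among all deposited peaks, and 310 sites were lost with lists of equal length.

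The comparison of LYFR cells with parental DMSO cells asked the same of resistance to both abemaciclib and fulvestrant. LYFR cells had both drugs in the medium and parental DMSO cells had neither, so drugs and resistance cannot be told apart here either. Gained sites were concentrated on the long arm of chromosome 8, near LRATD2 (56 gained, 0 lost), MYC, a transcription factor that drives growth (47 and 0), POU5F1B (45 and 0), ASAP1 (41 and 0) and SYBU (39 and 0). The gains ran along a stretch with many genes. The number of copies of this stretch was not measured, so opening at these genes cannot be told apart from more copies. Sites were lost near IGF1R, a growth factor receptor (0 gained, 5 lost), XBP1, a factor of the unfolded protein response (0 and 3), GATA3, a luminal transcription factor (0 and 2), CCND1, the cyclin partner of CDK4 and CDK6 (0 and 2), and ESR1, the oestrogen receptor (0 and 1). Lost distal sites carried the oestrogen response element in 7.13% of cases, against 0.792% of common distal sites, and the GATA motif in 24.1%, against 8.81%. Sites were gained near IFI27, an interferon-induced gene (6 gained, 0 lost), whose promoter was open in the LYFR list only.

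There were 3014 gained sites (6.03%, 5.82 to 6.24) and 1029 lost (2.06%, 1.94 to 2.19). TMEM74 and OXR1 had 29 gained and 0 lost sites, TRHR and ANGPT1, a vascular growth factor, 19 and 0, and PKHD1L1 17 and 0. Promoters of POU5F1B, TMEM74, TRHR and ANGPT1 were open in the LYFR list only, and those of LRATD2, MYC, ASAP1, SYBU, OXR1 and PKHD1L1 in both lists. On chromosome 8 from 105000001 to 131000000, bounds also chosen after the peaks were seen, the LYFR list had 2027 of its 50000 highest peaks and parental DMSO 438, a ratio of 4.63. LYR had 537. Of all its peaks LYFR had 8483 there (4.43%) and parental DMSO 1334 (0.854%). The window from 110000001 to 115000000 had 221 gained of 255 sites (86.7%, 81.9 to 90.6), that from 105000001 to 110000000 had 301 of 382 (78.8%) and that from 125000001 to 130000000 had 496 of 723 (68.6%). On chromosome 12 from 5000001 to 31000000 LYFR had 60 of its highest peaks against 322. Without the 16 windows in which the number of highest peaks differed 2-fold or more, an alternative chosen after the data were seen, 1752 sites were gained.

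**Figure D2:**
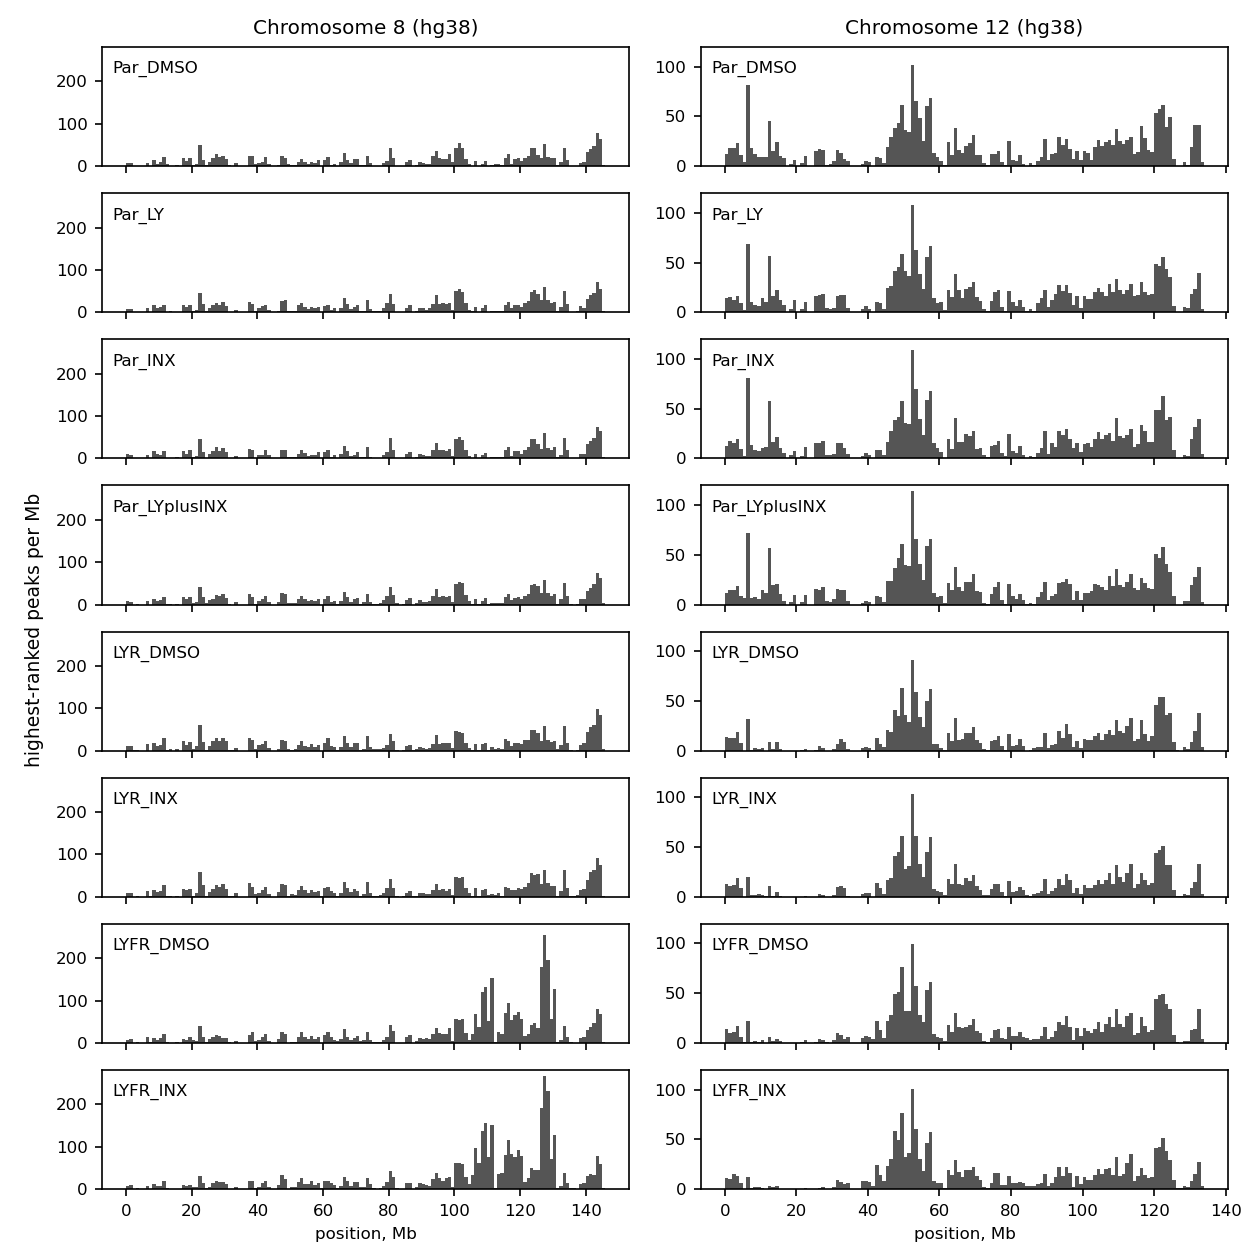
Number of peaks among the 50000 highest of each of the 8 lists per Mb along chromosome 8 (left) and chromosome 12 (right). LYFR had 2027 such peaks from 105000001 to 131000000 on chromosome 8 against 438 in parental DMSO, and LYR and LYFR had 77 and 60 from 5000001 to 31000000 on chromosome 12 against 322.

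DSCAM had 0 gained and 7 lost sites and PRKCE, protein kinase C epsilon, 0 and 4; RGS7, CREBL2, LMNTD1, SLC2A3, XYLT1, IER3 and CD9 had 0 and 3. Promoters of DSCAM, RGS7 and SLC2A3 were closed in both lists, that of XYLT1 was open in the DMSO list only, and those of IGF1R, PRKCE, CREBL2, LMNTD1, IER3, CD9, XBP1, GATA3, CCND1 and ESR1 were open in both. CREBL2, LMNTD1, SLC2A3 and CD9 lie in the chromosome 12 region. The strongest lost sites were in introns of DSCAM (chromosome 21, 40320510 to 40321708, area 5420) and PRKCE (chromosome 2, 46073410 to 46074083, area 3024) and in a UTR exon of IGF1R (chromosome 15, 98889934 to 98890615, area 3880.5, 91 bp from a transcription start). The strongest gained sites near LRATD2 (chromosome 8, 126503037 to 126507171, area 19564), MYC (chromosome 8, 127752958 to 127755266, area 6485) and POU5F1B (chromosome 8, 127508826 to 127510423, area 7838) lay outside protein-coding genes.

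Among the fixed gene lists, luminal breast identity genes had 0 gained and 9 lost sites, with 6 members losing and 0 gaining (percentile 0.660 of random lists). Cyclins, CDKs and CDK inhibitors had 0 gained and 4 lost (percentile 1.51), near CCND1 (2), CCND3 (1) and CDKN1B, a CDK inhibitor on chromosome 12 (1); CCND3 and CDKN1B were chosen after their values were seen. Interferon response and antigen presentation genes had 9 gained and 1 lost (percentile 98.8), of which IFI27 had 6 gained. Oestrogen receptor targets had 48 gained and 18 lost sites (percentile 97.4): 12 members lost sites, XBP1 and CCND1 among them, and MYC alone gained on balance. AP-1 and related bZIP factors had 0 gained and 3 lost (percentile 3.61), with 2 lost near FOSL2, a FOS family member. Senescence-associated secretory genes had 8 gained and 1 lost (percentile 94.5): IGFBP7, with 3 gained and 0 lost, had a promoter open in the LYFR list only, and TNFRSF11B, on the chromosome 8 region, had 2 and 0 with a promoter open in both lists. Growth factor receptors and adaptors had 7 gained and 8 lost (percentile 24.0), with EGFR at 3 and 0 and the adaptor GAB2 at 0 and 2. Basal and mesenchymal genes had 3 and 4 (percentile 22.97), with TP63, a basal cell factor, at 0 and 3 and a closed promoter in both lists. Apoptosis regulators had 2 and 0 (percentile 77.8), both near BCL2L1, which encodes the survival protein BCL-xL. E2F targets had 0 and 0 (percentile 37.5), markers of other cell types 0 and 0 (percentile 39.1) and housekeeping genes 2 and 1 (percentile 60.6). Promoters of FOSL2, EGFR, GAB2, BCL2L1, CCND3 and CDKN1B were open in both lists.

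Of the 912 lost distal sites 65 carried the oestrogen response element (5.54 to 8.99%), above every matched draw (highest 1.97%), and 220 the GATA motif (21.4 to 27.0%; highest matched draw 17.5%). RUNX was found in 7.02% of lost against 2.82% of common sites (highest matched draw 5.81%), CRE/ATF in 0.987% against 0.371%, AP-1 in 12.7% against 14.5%, TEAD in 10.2% against 10.1%, NF-kB in 1.64% against 2.87%, AP-2 in 7.24% against 12.03%, E2F in 0.548% against 0.746% and CTCF in 0.329% against 7.12%. FOX, at 19.3% against 13.3%, lay inside the range of the matched draws (14.3 to 23.6%). Among 2703 gained distal sites IRF was found in 4.40% against 2.03% (highest matched draw 3.59%) and NFY in 5.51% against 3.48% (highest 4.99%). The AP-1 share of gained sites was 12.5%, against 15.4% of common sites. TEAD was found in 12.1% against 10.4%, FOX in 13.2% against 13.4%, GATA in 6.51% against 6.34%, GRHL in 1.81% against 2.89%, SP/KLF in 0.703% against 1.41%, E2F in 0.185% against 0.701%, ERE in 0.333% against 0.554% and CTCF in 0.185% against 5.74%. These shares pool sites that differed: in the 1166 gained distal sites of the chromosome 8 windows of changed peak number GATA was found in 10.2%, AP-1 in 8.92%, TEAD in 9.78% and FOX in 11.9%, and in the 1519 outside all such windows in 3.75%, 15.2%, 13.96% and 14.3%. Promoters made up 10.3% of gained and 11.4% of lost sites, against 37.8% of common sites. With all deposited peaks the oestrogen response element was found in 1.496% of lost and 0.663% of common distal sites, and with the 25000 highest in 11.4% of lost sites.

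**Figure D3:**
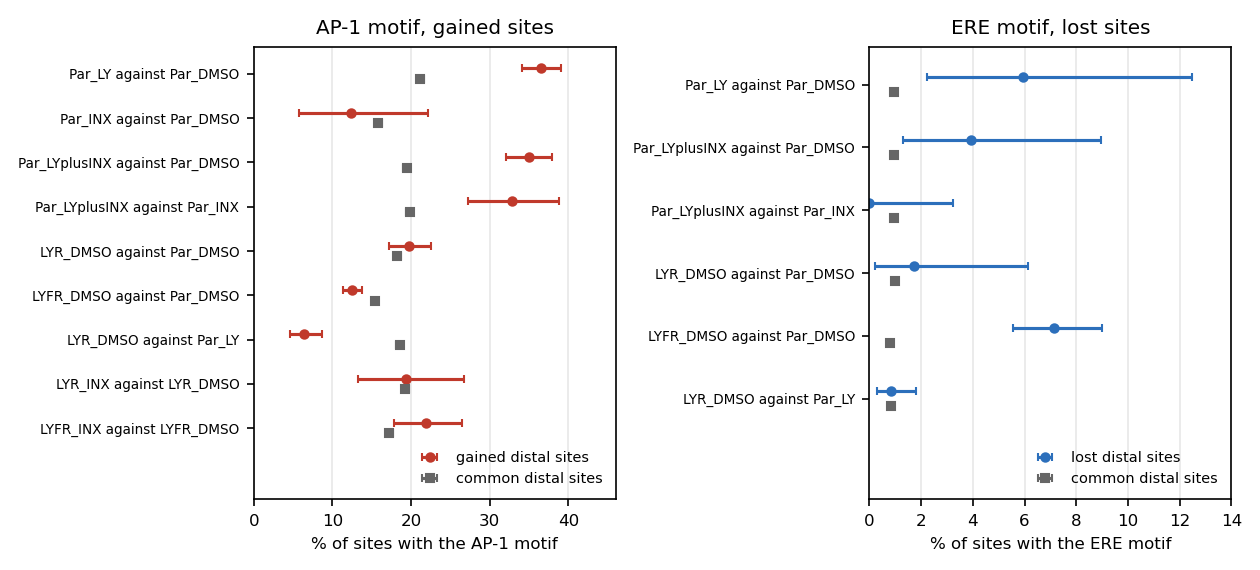
Share of distal sites with the AP-1 motif among gained sites (left, red) and with the oestrogen response element among lost sites (right, blue), each beside common distal sites (grey squares), in comparisons with enough changed distal sites; bars are exact 95% binomial intervals that cover counting error only. AP-1 was at 36.6% with abemaciclib and 12.5% in LYFR, and the oestrogen response element at 7.13% in LYFR and 1.74% in LYR.

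LYR and LYFR cells shared 430 gained sites against parental DMSO (39.9% of the 1078 of LYR; 54.98 for independent sets) and 79 lost sites (2.80 for independent sets). Of the sites gained in LYR, 80.7% had a peak in the LYFR list (simulated 97.4%). Sites gained with abemaciclib overlapped 192 of those gained in LYR (31.1 for independent sets) and 189 of those gained in LYFR (82.8), and the lost sites 46 of those lost in LYFR (2.63). All of these overlaps again share the DMSO list. LYR and LYFR also had fewer of the highest peaks in the same regions, as on chromosome 12 from 5000001 to 31000000 (77 and 60 against 322). Lost sites in such regions can add to the 79, and the overlap was not counted without them.

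The comparison of LYR cells with parental cells on abemaciclib put both under 500 nM abemaciclib. LYR cells lacked sites that parental cells on abemaciclib had: PMEPA1 had 0 gained and 14 lost sites and GPRC5A 0 and 13, with promoters open in both lists; GPRC5A lies in the chromosome 12 region that had fewer peaks in LYR. PLEKHA5, with 0 gained and 3 lost sites, lies in the same region. SMAD3, a mediator of TGF-beta signalling, and KRT8, a luminal keratin, had 0 gained and 3 lost sites, and CACNA1H had 5 gained and 0 lost. The p53 motif was found in 2.35% of lost distal sites against 0.140% of common ones, and TEAD in 18.6% against 11.3%. Gained distal sites carried NFY in 12.5% of cases against 3.55%, and AP-1 in 6.35% against 18.5%. With all deposited peaks p53 was found in 0.422% of lost against 0.0987% of common sites, and NFY in 4.86% of gained against 2.80%.

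The counts were 783 gained sites (1.57%) and 798 lost (1.60%), and 1241 and 1256 with lists of equal length. PLEKHA5, MAPK4, C3orf14 and LIMA1 had 0 gained and 3 lost sites and GPRC5D and AEBP2 0 and 2; the promoter of MAPK4 was open in the abemaciclib list only, that of GPRC5D closed in both, and those of SMAD3, KRT8 and the others open in both. HDAC4 had 4 gained and 0 lost sites, OLFM1, BAHCC1, EIPR1, XXYLT1, OR1F1 and SPATA13 3 and 0, RARA 2 and 0 and CCNE1, the cyclin partner of CDK2, 1 and 0, all with promoters open in both lists like that of CACNA1H. C13orf46, with 4 and 0, and TMEM235, with 3 and 0, had closed promoters, and ESR1 had 0 and 1. The strongest lost site near PMEPA1 lay in its intron (chromosome 20, 57662184 to 57665362, area 6774), that near GPRC5A was the site gained with abemaciclib (chromosome 12, 12906901 to 12909517, area 6324), and that of PLEKHA5 lay in its intron (chromosome 12, 19130544 to 19131353, area 2045). The strongest gained sites lay in introns of CACNA1H (chromosome 16, 1192737 to 1194106, area 6512) and HDAC4 (chromosome 2, 239274976 to 239275699, area 2975) and near C13orf46 in an intron of RASA3 (chromosome 13, 113981095 to 113981562, area 1830.3). The first 5 Mb of chromosome 16, which holds CACNA1H and OR1F1, had the highest gained share, 41 of 431 sites (9.51%, 6.91 to 12.7).

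The AP-1 motif was carried by 38 of 598 gained distal sites (4.54 to 8.62%; lowest matched draw 11.04%) and 177 of 724 lost ones (24.4%, 21.4 to 27.7) against 21.8%. NFY (9.99 to 15.5%) and p53 (17 of 724, 1.37 to 3.73%) lay above every matched draw, the highest of which were 6.86% and 0.829%. Gained sites also differed in SP/KLF (3.34% against 1.38%), FOX (8.19% against 14.5%), GATA (5.52% against 8.36%), SOX (1.51% against 2.47%), GRHL (1.51% against 2.40%) and CTCF (0.669% against 5.22%). Lost sites differed in GATA (15.9% against 10.1%), NF-kB (4.14% against 2.75%) and NFY (1.38% against 2.73%). FOX was found in 16.4% of lost sites against 15.6%, ERE in 0.829% against 0.849%, E2F in 0.276% against 0.546% and CTCF in 0 of 724. Gained sites carried ERE in 1.34% of cases against 1.03%, TEAD in 7.02% against 9.84% and E2F in 0.502% against 0.689%. Promoters made up 23.6% of gained and 9.27% of lost sites. Of the lost sites, 99.9% had a peak in the combination list and 30.3% in the parental DMSO list (simulated 95.7%). That simulated value comes from common sites, which have a peak in LYR by definition, whereas the lost sites have none there. Of the gained sites, 48.5% had a peak in parental DMSO. All 12 gene lists lay between percentiles 8.33 and 90.9. Gained and lost sites numbered 169 and 106 among the 25000 highest peaks and 37694 and 42934 among all deposited peaks.

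The comparison of INX-315 with DMSO in LYR cells asked what CDK2 inhibition adds to abemaciclib once cells are resistant to it. Sites were gained near SLC12A7, a potassium-chloride cotransporter (3 gained, 0 lost), the adaptor SHB (3 and 0), the transcription factor USF2 (2 and 0) and DUSP5, a phosphatase of ERK (2 and 0), with promoters open in both lists. Most of the gained sites, 82.5% of 166 (75.9 to 88.0), had a peak in parental cells on abemaciclib and 4.82% (2.10 to 9.27) had one in parental DMSO, against simulated values of 97.99% and 91.3%. Among the 50000 highest of that abemaciclib list were 18.7% of the 166 (simulated 65.8%). The simulated values come from common sites, which have a peak in LYR by definition, whereas the gained sites have none there. The parental DMSO list was closer to that of LYR (Jaccard index 0.710) than the abemaciclib list was (0.676). Part of the shortfall in parental DMSO therefore follows from the definition. Conversely, the 1718 sites gained with abemaciclib in parental cells were looked up. Of these, 67.6% had a peak in LYR and 88.5% in LYR with INX-315 (simulated 99.2% and 99.5%). Among the 50000 highest were 11.4% (9.89 to 12.9) in LYR and 38.6% (36.3 to 41.0) in LYR with INX-315 (simulated 69.4% and 69.7%). In LYFR cells 47.2% had a peak without and 76.4% with INX-315 (simulated 95.1% and 97.3%). There 11.2% (9.72 to 12.8) without and 32.5% (30.3 to 34.8) with INX-315 were among the 50000 highest (simulated 63.1% and 61.0%).

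In LYR cells 166 sites were gained (0.332%) and 29 lost (0.0580%), and 369 and 120 with lists of equal length. EEIG1 and PALM2AKAP2 had 2 gained and 0 lost sites with promoters open in both lists, and KEL, LILRB1, MAGEC2 and MGAM 1 and 0 with closed promoters. ARSF, CA6, DLGAP2 and ABCC6 lost 1 site with a closed promoter, NKX1-2 lost 1 site and its open promoter, and CEP120, CD9, NEDD4, PTPRS and BEND3 lost 1 site with promoters open in both lists. For each of the first genes, the strongest gained site lay near SLC12A7 (chromosome 5, 1047826 to 1049968, area 4674), SHB (chromosome 9, 37986498 to 37987712, area 1629.8) and USF2 (chromosome 19, 35264375 to 35265879, area 2118), and the strongest lost sites near ARSF (chromosome X, 3142633 to 3143541, area 2400.2), CA6 (chromosome 1, 8939430 to 8939980, area 1142) and NKX1-2 (chromosome 10, 124440343 to 124440936, area 1170.1). IRF was found in 14 of 145 gained distal sites (9.66%, 5.38 to 15.7) against 2.37%, which equals the highest matched draw. AP-1 was at 19.3% in both gained and common distal sites. TEAD was found in 13.8% against 9.94%, FOX in 14.5% against 13.9%, and GATA in 8.28% against 8.34%, and CTCF, ERE and E2F in 0 of 145, which allows shares up to 2.51%. Of the gene lists, senescence-associated secretory genes had 2 gained sites (percentile 98.1), near IGFBP3 and LIF, oestrogen receptor targets 1 lost (percentile 2.49), near RARA, and AP-1 and related bZIP factors 1 lost (percentile 1.43), near FOSL2, genes chosen after their values were seen, with 1 site each and promoters open in both lists; the other 9 lay between percentiles 42.0 and 92.1. Gained sites numbered 15 among the 25000 highest peaks and 41785 among all deposited peaks, with which the bZIP list stood at 33 gained minus lost.

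The comparison of INX-315 with DMSO in LYFR cells asked the same under abemaciclib and fulvestrant. SNTB1 (4 gained, 0 lost) and SAMD12 (3 and 0), both in the chromosome 8 region, and KLF6, a zinc finger transcription factor, NAMPT, an enzyme of NAD salvage, and SPTBN1, a spectrin (2 and 0 each), gained sites, with promoters open in both lists. Of the 409 gained sites, 70.4% (65.7 to 74.8) had a peak in parental cells on abemaciclib and 16.1% (12.7 to 20.1) in parental DMSO, against simulated values of 93.6% and 86.5%. These simulated values come from common sites, which have a peak in LYFR by definition, whereas the gained sites have none there. AP-1 was found in 21.9% of gained and 17.2% of common distal sites; with the 25000 highest peaks the direction turned, at 2 of 21 gained sites (9.52%, 1.17 to 30.4) against 18.7%.

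In LYFR cells 409 sites were gained (0.818%) and 33 lost (0.0660%), and 855 and 157 with lists of equal length. RPAP3, DDC, PCED1B and NECAB2 had 2 gained and 0 lost sites with promoters open in both lists and KCND3 2 and 0 with a closed one. SMCO1, with a closed promoter, and BIN3 and NRBP2, with promoters open in both lists, had 0 gained and 2 lost sites; MMP25, FAM117B, NARS2, ANKRD10, FGFR4, a growth factor receptor, and PPIA lost 1 site with promoters open in both lists, and TOX3 1 with a closed one. Among gained sites the strongest lay in introns of SNTB1 (chromosome 8, 120734511 to 120735875, area 2930.0) and SAMD12 (chromosome 8, 118614059 to 118615185, area 1632) and near RPAP3 (chromosome 12, 47652494 to 47653126, area 1111), and the strongest lost sites near SMCO1 (chromosome 3, 196517912 to 196518351, area 1450.4), BIN3 (chromosome 8, 22679068 to 22680917, area 2834) and NRBP2 (chromosome 8, 143842484 to 143843646, area 2093). Of 365 gained distal sites 80 carried AP-1 (17.8 to 26.5%; highest matched draw 27.1%). RUNX was found in 3.84% against 2.44%, STAT in 1.92% against 0.999%, IRF in 4.38% against 2.62%, FOX in 17.5% against 13.6%, GATA in 9.04% against 6.64%, TEAD in 10.96% against 10.7%, ERE in 0.274% against 0.591% and NF-kB in 1.64% against 2.84%, and CTCF and E2F in 0 of 365, which allows up to 1.01%. E2F targets had 0 gained and 1 lost site (percentile 0.985), near RRM2, a nucleotide reductase subunit chosen after its value was seen (promoter open in both lists), and housekeeping genes 2 and 1, with 2 gained near YWHAZ (promoter open in both lists); the 11 lists other than E2F targets lay between percentiles 26.9 and 94.8. Gained sites numbered 23 among the 25000 highest peaks and 48545 among all deposited peaks. Sites gained with INX-315 in LYR and in LYFR shared 24 sites (1.15 for independent sets; these comparisons share no list), and those gained with INX-315 in parental and in LYR cells shared 1 (0.218). Over the 120 list results of the 10 comparisons, 8 lay outside the middle 95% of random lists. This number cannot be set against 5%, since lists share genes and comparisons share peak lists. Some results also rest on few sites or none, as for both drugs against abemaciclib, where gained minus lost was 0 in all 12 lists.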

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

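The tests of a longer list and of fulvestrant in the medium were chosen after the results were seen.

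Peaks on contigs outside chromosomes 1 to 22 and X, which no comparison used, made up a larger share of the 7 other lists than of the parental DMSO list (0.199%, 0.177 to 0.222), which served as the level of the control. In 5 of them the shares were 0.247% with INX-315, 0.280% with both drugs, 0.295% in LYR with INX-315, 0.259% in LYFR and 0.343% in LYFR with INX-315, each with an interval above that of the control. Those with abemaciclib (0.235%, 0.214 to 0.258) and in LYR (0.231%, 0.210 to 0.254) had intervals that overlap that of the control. With lists of equal length the shares of the 5 lists were 0.242%, 0.275%, 0.280%, 0.246% and 0.330%. Decoy contigs held 132 of these peaks in the control list and 330 in LYFR with INX-315. No biological explanation was tested.

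The AP-1 motif in the distal sites gained with abemaciclib (36.6%), a set that includes sites near PMEPA1, was set against 3 technical explanations. Against GC content, the highest of 10000 draws matched on it reached 27.1%. Against weaker peaks, draws of common sites matched on area reached 22.3% at most. If a longer list than that of DMSO brought AP-1 whatever the cells, LYFR should show it too. There the share outside windows of changed peak number was 15.2% against 15.3% of common sites. In LYR, also a longer list, the share was 19.7% (17.2 to 22.5) against 18.3%. With all deposited peaks it was 15.6% (15.3 to 16.0) against 12.2% in LYR, and 10.4% against 11.7% in LYFR. These LYFR shares include the windows of changed peak number, those of chromosome 8 among them. They therefore do not repeat the comparison made outside the windows. LYFR is another line with fulvestrant in the medium, so an effect of list length in parental cells stays open. A response of the cells to abemaciclib may be the source, as a hypothesis found and weighed on the same data, and fresh against frozen cells stays open because the labels do not give it.

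The sites gained on chromosome 8 in LYFR, near MYC and LRATD2, were set against 3 explanations. Background raised over the peak threshold by more copies was weighed as the source of all these sites by their AP-1 share. It was 8.92% (7.35 to 10.7), against 2.76% (2.45 to 3.10) at random positions of the windows outside every peak of the 8 lists. Leaving out peaks removes open sites with the motif beforehand, and the positions were not matched on GC content. The difference goes against background as the only source without excluding it. TEAD (9.78% against 5.13%), FOX (11.9% against 8.75%), CTCF (0.257% against 0) and GATA (10.2% against 18.4%) also had intervals apart from those of random positions, while ERE (0.515% against 0.34%) and E2F (0.172% against 0.12%) did not. Background at part of the sites stays open, since AP-1 and GATA lay between random positions and the sites gained outside windows of changed peak number (15.2% and 3.75%). More copies that raise every site and opening of regulatory sites alone cannot be told apart. Of the shared sites 77.0% (72.3 to 81.2) ranked higher in LYFR, against 33.3% elsewhere, and of the shared CTCF sites 66.7% (10 of 15, 38.4 to 88.2) did, against 23.4% elsewhere (508 of 2169). The rise of CTCF sites over elsewhere goes against opening of regulatory sites alone, which is left open because both intervals hold the 75% set beforehand, the CTCF sites number 15 and the windows were picked for having more of the highest peaks.

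The oestrogen response element in the distal sites lost in LYFR (7.13%), where sites near XBP1 and CCND1 were lost as well, was set against 3 explanations. Loss of chromosome segments is argued against by the share outside windows of changed peak number, 7.43% (5.76 to 9.41) against 0.798% of common sites, and GC content by matched draws that reached 1.97% at most. Fulvestrant in the medium and the resistant line itself cannot be told apart, since the LYFR libraries alone had fulvestrant. Without it, the share was 1.74% in LYR (2 of 115 lost sites, 0.211 to 6.14) against 0.972% of common sites. In parental cells, also without it, it was 5.94% (6 of 101, 2.21 to 12.5) with abemaciclib against 0.959%, and 3.94% (5 of 127, 1.29 to 8.95) with both drugs against 0.963%, so sites with the element were also lost without fulvestrant. Draws matched on GC content reached 5.94% and 6.30% for these 2 parental sets.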

How the results depend on the processing

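The alternative without windows of changed peak number was chosen after the results were seen. No paired analysis was possible because each group has 1 list made from both libraries. Leaving out each library in turn was planned and not run, since the lists hold no values per library. Unless a sentence says otherwise, the cause of a difference was not tested. Log2 values are the ratio of gained to lost sites.

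With the 25000 highest peaks fewer peaks can be called, by construction. Abemaciclib against DMSO had 200 gained and 8 lost sites (log2 4.64), with AP-1 in 33.5% of gained distal sites. INX-315 against DMSO had 0 gained and 0 lost, and so had both drugs against abemaciclib. Both drugs had 109 and 8 against DMSO (log2 3.77; AP-1 38.4%) and 12 and 5 against INX-315. LYR had 179 and 6 against DMSO (log2 4.90) and 169 and 106 against abemaciclib (log2 0.67). LYFR had 1004 and 188 (log2 2.42), with ERE in 11.4% of lost distal sites. INX-315 gave 15 and 1 in LYR (log2 3.91) and 23 and 4 in LYFR (log2 2.52), where the direction of AP-1 turned, at 9.52% of gained distal sites (2 of 21, 1.17 to 30.4) against 18.7% of common ones.

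With all deposited peaks more peaks can be called, by construction. Abemaciclib against DMSO had 57547 gained and 23081 lost sites (log2 1.32; AP-1 21.1%), and INX-315 against DMSO 26103 and 18354 (log2 0.51). Both drugs had 45625 and 26555 against DMSO (log2 0.78; AP-1 19.98%), 14158 and 30330 against abemaciclib, and 35417 and 23919 against INX-315 (log2 0.57; AP-1 19.9%). LYR had 47578 and 18083 against DMSO (log2 1.40; AP-1 15.6%) and 37694 and 42934 against abemaciclib (log2 -0.19). LYFR had 55710 and 27145 (log2 1.04; AP-1 10.4%), with ERE in 1.496% of lost distal sites, 73 gained minus lost sites near interferon response genes and -123 near luminal genes. INX-315 gave 41785 and 23315 in LYR (log2 0.84) and 48545 and 25931 in LYFR (log2 0.90; AP-1 15.03%). In LYR with INX-315 the AP-1 and related bZIP list stood at 33, the opposite sign of the -1 reported.

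With lists of equal length fewer peaks are left to overlap, by construction. Lost sites numbered 350 for abemaciclib against DMSO (log2 2.30), 12 for INX-315 against DMSO, 309 for both drugs against DMSO (log2 1.96), 259 for both drugs against INX-315 (log2 0.70) and 310 for LYR against DMSO (log2 1.80). Both drugs against abemaciclib had 66 gained and 6 lost, and LYR against abemaciclib 1241 and 1256. The log2 ratio for LYFR against DMSO was 1.02. INX-315 gave 369 and 120 in LYR (log2 1.62) and 855 and 157 in LYFR (log2 2.45). Sites gained against parental DMSO cannot differ here by list length, as that list is the shortest.

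With peaks ranked by -log10 p, lost sites numbered 52 for abemaciclib against DMSO (log2 4.63; AP-1 43.7%), 67 for both drugs against DMSO (log2 3.79; AP-1 42.9%) and 37 for both drugs against INX-315 (log2 2.46; AP-1 44.3%). They numbered 73 for LYR (log2 3.44) and 628 for LYFR against DMSO (log2 1.83; AP-1 13.9%), and 503 for LYR against abemaciclib (log2 0.22). INX-315 against DMSO had 17 gained and 0 lost, and both drugs against abemaciclib 0 and 0. INX-315 gave 74 and 7 in LYR (log2 3.40) and 16 lost in LYFR. Near C3orf14 the difference for both drugs against DMSO was -1, the opposite sign of the 3 reported.

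With 50% of the peak covered as overlap, more sites count as missing by construction. Abemaciclib against DMSO had 3636 gained and 697 lost (log2 2.38), and INX-315 against DMSO 590 and 99. Both drugs had 2682 and 809 against DMSO (log2 1.73), 98 and 55 against abemaciclib and 882 and 658 against INX-315 (log2 0.42). LYR had 2456 and 551 against DMSO (log2 2.16) and 1936 and 1956 against abemaciclib (AP-1 9.89%). LYFR had 5180 and 2306 (log2 1.17; ERE 5.13%). INX-315 gave 759 and 193 in LYR and 1615 and 231 in LYFR (log2 2.81).

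Without windows of changed peak number the log2 ratio was 3.39 for LYR against DMSO. LYFR against DMSO had 1752 gained sites (log2 0.89; AP-1 15.2%).

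With 50 bp on each side of the summit less sequence is searched, by construction. AP-1 was then found in 25.6% of distal sites gained with abemaciclib, 25.1% with both drugs, 20.7% with both drugs against INX-315, 11.97% in LYR, 8.32% in LYFR, 3.51% in LYR against abemaciclib and 16.99% with INX-315 in LYFR.

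Other motifs moved as well. With all deposited peaks p53 was found in 0.356% of sites gained with abemaciclib against 0.0903% of common sites, and in 0.422% of sites lost in LYR against abemaciclib against 0.0987%; with 50% of the peak covered these shares were 0.822% and 1.32%, and the second was 1.04% (1 of 96) with the 25000 highest peaks. With all deposited peaks NFY was found in 3.99% of sites gained in LYR against DMSO (2.93% of common sites) and 4.86% against abemaciclib (2.80%), IRF in 3.56% in LYFR (2.15%) and 4.85% with INX-315 in LYR (2.41%), TEAD in 10.1% with abemaciclib (8.89%) and GATA in 15.2% of sites lost in LYFR (8.82%). Ranked by -log10 p, NFY was found in 9.71% and 16.3% and IRF in 5.51% and 19.7% of the same gained sets, and without windows of changed peak number IRF in 5.27% in LYFR.

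With promoters within 2 kb more sites count as promoters, by construction. The shares of gained and lost sites were 14.7% and 30.5% for abemaciclib, 15.4% and 30.6% for both drugs against DMSO and 14.8% and 23.7% against INX-315. They were 23.8% and 25% for LYR, 15.8% and 19.2% for LYFR, 33.8% and 15.04% for LYR against abemaciclib and 19.9% and 27.6% with INX-315 in LYR. The share of gained sites was 16.5% for INX-315 against DMSO and 16.9% with INX-315 in LYFR.

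Counts of other values follow. With genes within 50 kb, 106 list results stayed within 1.5 times the value reported and 14 moved; with lists of equal length 83 stayed and 37 moved, and with all deposited peaks 1 stayed, 118 moved and 1 changed sign. Of values near named genes, 158 stayed and 23 moved without windows of changed peak number, 173 stayed and 8 moved with lists of equal length, 143 stayed and 38 moved with 50% of the peak covered. For the same values 18 stayed and 163 moved with the 25000 highest peaks, 22 stayed and 159 moved with all deposited peaks, and 57 stayed, 123 moved and 1 changed sign with peaks ranked by -log10 p. All 18 overlaps between comparisons stayed within 1.5 times the reported number with 50% of the peak covered.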

Other observations

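The genes named in this part were chosen after their values were seen, except IFI27 and MYC, which the fixed rules named above. No alternative was run on the promoter states given here.

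Promoters of some list members were open in only some of the 8 lists. OAS2 and IFI27, which respond to interferon, were open in the abemaciclib list, the list of both drugs and all 4 lists of resistant cells, and closed in parental DMSO and INX-315. IFIT3, of the same gene list, differed from them in being closed with both drugs. Such switches were also seen in markers of other cell types, DCN and LUM among them. Of these 20 markers, 8 to 11 were open per list and 6 in all 8 lists. IFI44L and the chemokine CCL2 were open in the 2 LYFR lists alone, and CCL20 and the keratin KRT17 in the 4 lists of resistant cells alone. TWIST1, a mesenchymal factor, was closed in these 4 lists and open in the 4 parental ones. AGR3, an oestrogen receptor target, was closed in both LYFR lists, and TFF1, another target, was closed in parental DMSO alone. JUNB, an AP-1 factor, was closed with abemaciclib, with both drugs and in LYR with INX-315. Closed means that no summit lay within 1 kb of a transcription start of the gene. A peak over the promoter whose summit lies further away also counts as closed.

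On chromosome 8, near MYC, in the windows picked for having more of the highest peaks in LYFR, 64.0% of 369 shared sites ranked higher in LYR (35.7% elsewhere), and 75.9% of 365 in LYFR with INX-315 (29.8% elsewhere). On chromosome 12, in 3 windows picked for having fewer of the highest peaks in LYFR, 1 of 228 shared sites ranked higher in LYR (0.439%, against 36.0% elsewhere) and 1 of 215 in LYFR (0.465%, against 33.7%); lower ranks were to be expected there from how the windows were picked. On chromosome 18, 2 windows had fewer of the highest peaks in resistant cells: from 55000001 to 60000000 parental DMSO had 52, LYR 14 and LYFR 14, and from 75000001 to 80000000 it had 56, LYR 13 and LYFR 12. The number of copies of these regions was not measured.

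Sites lost in LYFR against parental DMSO had a peak in LYR in 92.3% of cases (simulated 99.8%), in parental cells on abemaciclib in 95.5% (simulated 99.7%) and in LYFR with INX-315 in 35.9% (simulated 98.8%). The simulated values come from common sites, which have a peak in LYFR by definition. The low share in LYFR with INX-315 follows in part from that. Sites gained with INX-315 in LYR had a peak in LYFR with INX-315 in 92.8% of cases (simulated 98.05%), and sites gained with INX-315 in LYFR had one in LYR with INX-315 in 87.5% (simulated 96.7%).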
